A study of Homo sapiens with 4 samples.

How the data were processed

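Gene expression was measured by RNA sequencing of cultured C4-2B-TaxR cells. Per the labels' protocols RNA was extracted with TRIzol, and libraries were made from 1 µg of total RNA with a TruSeq RNA kit. Cells were treated for 48 h with vehicle, 10 nM docetaxel, 2 µM SR2211 or both, and each of the 4 groups had 1 library. Groups were taken from the treatment label of each sample.

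The authors deposited 1 gene table per library. Per the file headers each table gives an Entrez gene number with its symbol, the RefSeq transcripts, a transcript length in bases, an expected count and an FPKM value. The expected counts are estimated reads per gene that need not be whole, as deposited and not normalized, with totals of 16.7 M for vehicle, 16.6 M for docetaxel, 16.2 M for SR2211 and 15.95 M for the combination. The FPKM values, which the authors computed, are scaled for transcript length and for library depth, are given to 2 decimals and are listed from 0.01 upward, so a gene that is not listed in a library is treated as being below that level. The submitters' processing notes name BWA, Bowtie and Cufflinks and the builds GRCh37 and hg19. Versions, the role of each tool and the quantifier that made the expected counts are not given in the sources used here. The plan made before the data were examined assumed that Cufflinks made the FPKM values with confidence bounds. The tables hold no such bounds and no status column, so the parts of the plan that needed them were not used. Whether counting used the strand of the reads is not given either, so a gene and its antisense partner cannot be separated.

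FPKM was used as deposited. Genes were matched by Entrez number between libraries, 35 symbols that were blank or had been turned into dates were restored from it, no symbol was repeated, and 21491 of 21600 numbers matched a RefSeq gene table of assembly GRCh38.p14. That table is of another build than the files and was used for names only, so no coordinates are given. A gene was called expressed when its mean FPKM over the 4 libraries was at least 1 (12780 genes). Changes are log2((FPKM + 1)/(FPKM + 1)), which understates the change of low genes, and a gene was counted as higher or lower at 1 or more in size, which is 2-fold. A typical gene at 1 FPKM rested on a median of 44.2 to 46.1 counts in these libraries. Folds are ratios of FPKM without a pseudocount and are given with exact Clopper-Pearson 95% intervals from the expected counts, rounded to whole numbers, which cover counting error only. These intervals are scaled to the FPKM ratio, which for some genes differs from the ratio of counts. No test and no p-value was computed, because 1 library per group leaves no replicate.

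Comparisons were docetaxel over vehicle, SR2211 over vehicle, combination over vehicle, combination over docetaxel and combination over SR2211. The change with each drug was correlated across expressed genes with the change with the same drug in the presence of the other. Departure from additivity was the log2 value of the combination, minus those of docetaxel and SR2211, plus that of vehicle. For 37 gene lists fixed in advance, the median log2 change of the expressed members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a percentile that describes these libraries (160 medians for lists with at least 5 expressed members). Members at least 1.5-fold and 2-fold different on the same scale were counted. The lists cover efflux transporters, the neighbourhood of ABCB1, tubulins, microtubule-associated genes, intrinsic, extrinsic and other cell death, survival genes, p53 targets, ATF4 and unfolded protein response, heat shock, NRF2, metallothioneins, mitosis, S phase, androgen receptor targets, cholesterol synthesis, fatty acid synthesis, LXR targets, ROR and clock genes, type 17 cytokines, interferon, NF-κB, immediate early genes, MYC and E2F, hypoxia, autophagy, neuroendocrine, epithelial and mesenchymal genes, DNA repair, senescence, ribosomal proteins, nuclear and mitochondrial respiration genes, histones and housekeeping genes.

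The groups, comparisons, thresholds, gene lists, markers of other cell types and the rule for naming genes were fixed before the data were examined. The rule names ABCB1, KLK3 and other genes tied to the treatment or the line. Some genes that the rule takes are not reported here. It also names the 12 highest and 12 lowest genes of each comparison with vehicle outside small RNAs, and the 6 genes each way with the largest smaller change of a drug's 2 comparisons. Finally it names the 6 each way with the largest departure from additivity, and up to 4 members of largest change in each list and comparison. SERF1B and LUZP6 were added after their values were seen. Genes of which at least 20% of the 31-base words of their GENCODE release 29 transcripts, on either strand, occur in transcripts of another listed gene are called genes with shared sequence and are reported as uncertain. Genes without such a transcript were treated alike, which made 1723 expressed genes in all, and 322 expressed small RNA genes were counted apart.

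Alternatives fixed in advance were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, rescaling to TPM and median-of-ratios factors. Alternatives added after seeing the data were requiring counting intervals to lie apart, removing the median change of each of 20 bins of GC content (known for 97.3% of expressed genes), and leaving out small RNAs and genes with shared sequence. The procedure was tested on simulated counts for the combination over vehicle with 200 changed genes among 12743. The changed genes were drawn only from those with a mean of at least 5 FPKM, so recovery below that level was not tested. The simulated counts held counting noise alone. It recovered 26% of those changed 2-fold, 100% of those changed 3-fold, 98% of those changed 4-fold and 100% of those changed 8-fold. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.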

Results

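RNA sequencing libraries were made from C4-2B-TaxR cells, a taxane-resistant derivative of the human prostate cancer line C4-2B that was grown with 5 nM docetaxel. Whether that docetaxel was removed before treatment is not given in the sources used here. Cells were treated for 48 h with vehicle, with 10 nM docetaxel (a taxane that stabilises microtubules), with 2 µM SR2211 (a ligand that inhibits the nuclear receptor RORγ), or with both drugs together. Each of the 4 groups had 1 library. The summed expected counts were 16.7 M for vehicle, 16.6 M for docetaxel, 16.2 M for SR2211 and 15.95 M for the combination, and the 10 genes with the most counts held between 4.29 and 4.41% of them. A gene was listed in the tables at 0.01 FPKM or more. The combination library listed 20370 genes, and the others listed 18965 (vehicle), 18969 (docetaxel) and 19038 (SR2211). Across the libraries 21600 genes were listed at least once, and 12780 of them had a mean of at least 1 FPKM and are called expressed here. With 1 library per group, no difference described here has a replicate check. The bracketed intervals are 95% exact intervals of the counts behind a fold and cover counting error only. Where levels are bracketed as well, they come first, with that of the reference library before that of the treated one.

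The title of the series concerns RORγ antagonists, expression of the drug efflux pump MDR1 and the response to taxanes, so the gene for MDR1 was examined first. ABCB1 (gene 5243), which encodes MDR1, was at 125 FPKM with vehicle, 138 FPKM with docetaxel, 84.6 FPKM with SR2211 and 61.6 FPKM with the combination. Relative to vehicle ABCB1 was 1.48-fold lower with SR2211 (1.44 to 1.53) and 2.04-fold lower with the combination (1.97 to 2.11), and it was 1.10-fold higher with docetaxel (1.07 to 1.13). The combination was 2.25-fold below docetaxel alone (2.17 to 2.33) and 1.37-fold below SR2211 alone (1.32 to 1.43) for ABCB1. KLK3 (gene 354), which encodes prostate-specific antigen and is a target of the androgen receptor, was at 1333 FPKM with vehicle, 1376 FPKM with docetaxel, 402 FPKM with SR2211 and 531 FPKM with the combination, 3.31-fold lower with SR2211 (3.24 to 3.39) and 2.51-fold lower with the combination (2.46 to 2.56) than with vehicle.

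**Figure D1:**
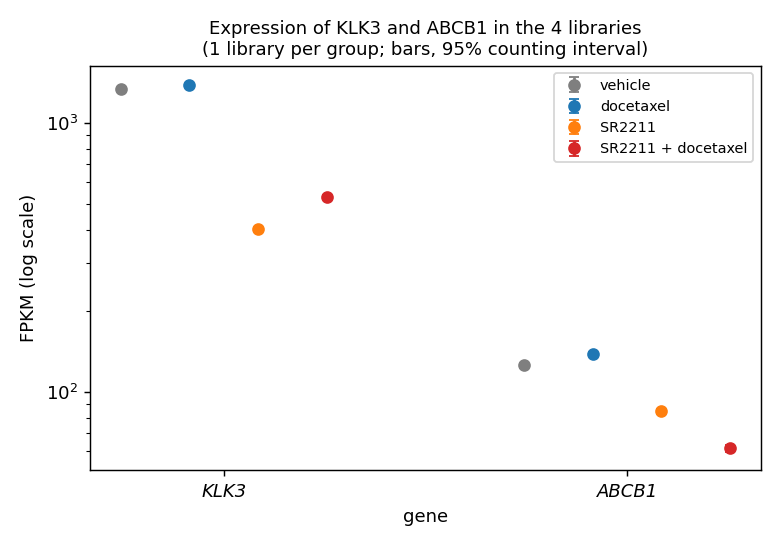
Expression of ABCB1 and KLK3 in the 4 libraries, in FPKM on a log axis, with 1 point per library and bars for the 95% counting interval. ABCB1 was lowest in the combination library at 61.6 FPKM, and KLK3 was lowest in the SR2211 library at 402 FPKM.

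Efflux transporters did not share one direction. Of the 12 genes of the taxane and multidrug efflux list, which holds ABCB1, 5 were expressed. Their median log2 change with SR2211, which is the value of ABCB1 itself, was −0.56, at percentile 0 among 10000 random lists of the same size matched on expression. Of the other four, ABCC4 was 2.03-fold lower with SR2211 (29.9 to 14.7 FPKM) and ABCC1 was 1.59-fold lower (30.0 to 18.8 FPKM), while ABCC5 was 1.71-fold higher (14.3 to 24.5 FPKM) and ABCC10 was at 5.13 and 7 FPKM. ABCC4 is also a member of the list of androgen receptor targets. In the combination the median was −0.44 over vehicle and −0.28 over docetaxel. Over vehicle ABCB1 and ABCC4 were at least 1.5-fold lower, and ABCC5 was at 24.5 FPKM. The genes that surround ABCB1 on chromosome band 7q21 had a median of 0.05 with SR2211 and 0.04 with the combination over 10 expressed members. Among those neighbours CROT, a peroxisomal carnitine transferase gene, was 2.25-fold lower with SR2211 (12.9 to 5.73 FPKM), RUNDC3B was 1.84-fold higher (1.73 to 3.19 FPKM), and DBF4, which encodes an activator of replication origins, was 2.03-fold lower with the combination (10.7 to 5.25 FPKM).

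Docetaxel was first compared with vehicle, which asks what the taxane alone did to cells selected for resistance to it. Among gene groups fixed in advance, the docetaxel library was close to the vehicle library. Across all gene lists no expressed member was 2-fold higher or lower on the log2(FPKM + 1) scale, and past 1.5-fold there was 1 histone gene, HIST1H4B (0.61 to 1.48 FPKM), and 1 interferon-stimulated gene, IFI27 (1.49 to 0.52 FPKM). The p53 targets had a median log2 change of 0.02 over 26 members, the mitosis genes 0.05 over 30 and the androgen receptor targets 0.05 over 27. CDKN1A, the p53 target that encodes the cell cycle inhibitor p21, was 1.26-fold higher (47.7 to 60.1 FPKM, 1.18 to 1.34). Other p53 targets went both ways, with TP53I3 higher (3 to 3.44 FPKM) and GADD45A (6.27 to 4.74 FPKM) and GDF15 (35.7 to 28.7 FPKM) lower. CEBPB, a stress-responsive transcription factor gene of the ATF4 list, was 1.52-fold lower (26.8 to 17.6 FPKM, 1.38 to 1.69), and the immediate early genes had a median of −0.19 (percentile 0.07), with DUSP5 at 2.65 and 1.86 FPKM and JUN at 11.9 and 9.77 FPKM. None of the 12 immediate early members was past 1.5-fold, and their median was −0.11 once the median change of each GC bin was removed. Ribosomal protein genes had a median of 0.15 (percentile 99.4), with RPL10A at 902 and 1054 FPKM and RPL19 at 1578 and 1837 FPKM.

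In all, 55 expressed genes were at least 2-fold higher and 68 at least 2-fold lower with docetaxel. Small RNA genes made up 45 of the 55 and 55 of the 68, and a further 9 and 11 were genes that share sequence with other genes or had no reference transcript in which to look for sharing, which leaves 1 and 2. Such genes are called uncertain from here on. Of the 12 highest genes outside the small RNAs, 10 were uncertain, and so were 10 of the 12 lowest. The highest were GAGE12I, GAGE7, GAGE5, MEF2B, LOC554249, GAGE2D, PVRIG2P, ABHD14A-ACY1, STAG3L5P, CDC37L1-AS1, LOC102724874 and NEDD8-MDP1, the GAGE genes being near-identical cancer/testis antigen copies. The lowest were GTF2IP1, URGCP-MRPS24, HYPK, SAPCD1, NPIPA2, BORCS8-MEF2B, DBNDD2, JMJD7-PLA2G4B, LOC102467223, LOC101929613, C14orf178 and FGF22. Of those with sequence of their own, FGF22, a fibroblast growth factor gene, was 3.66-fold lower (2.71 to 0.74 FPKM, 1.54 to 10.0), and the non-coding CDC37L1-AS1 was at 1.40 and 3.81 FPKM, from 7 and 14 counts. LOC102467223 was at 1.46 FPKM with vehicle and not listed with docetaxel. Requiring the counting intervals to lie apart as well left 9 higher and 12 lower genes. Over the 6500 genes with a mean of at least 10 FPKM, the log2 change had a standard deviation of 0.15 and a rank correlation of −0.64 with the GC content of the transcripts, across genes that are not independent replicates.

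SR2211 was compared with vehicle to ask what the inhibitor changed without added docetaxel. Androgen receptor targets were the gene group furthest from vehicle. Of 27 expressed members 19 were at least 1.5-fold lower and 16 at least 2-fold lower, none was 1.5-fold higher, and the median log2 change was −1.34 (percentile 0). C1orf116 was 9.37-fold lower (45.7 to 4.88 FPKM, 8.49 to 10.4) and PMEPA1, an inhibitor of TGF-β signalling, was 7.62-fold lower (39.3 to 5.16 FPKM, 6.86 to 8.47). KLK2, a kallikrein gene, was 5.69-fold lower (150 to 26.3 FPKM, 5.36 to 6.06). The same group was at 0.05 with docetaxel.

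The 12 lowest genes with SR2211 included several of these targets and all had sequence of their own. PGC, which encodes the protease precursor progastricsin, was 18.3-fold lower (19.6 to 1.07 FPKM, 12.2 to 28.9), and CHRNA2, a nicotinic receptor subunit gene, was 111-fold lower (5.57 to 0.05 FPKM, 37.8 to 543). ZNF385B was 8.70-fold lower, ST6GALNAC1, a sialyltransferase gene, 6.82-fold, NPPC, which encodes C-type natriuretic peptide, 6.34-fold, EAF2 6.26-fold, SLC45A3, the prostein gene, 5.78-fold (26.6 to 4.60 FPKM) and ASRGL1 5.44-fold. Among the 12 highest, CA1, which encodes carbonic anhydrase 1, was 9.31-fold higher (21.1 to 196 FPKM, 8.41 to 10.3). PLA2G2A, a secreted phospholipase gene, was 12.1-fold higher (0.81 to 9.79 FPKM, 6.71 to 23.9), MATN2, a matrix protein gene, 11.6-fold (0.79 to 9.14 FPKM, 8.77 to 15.5), PLD1, a phospholipase D gene, 6.55-fold (0.91 to 5.96 FPKM), ELOVL6, a fatty acid elongase gene, 5.02-fold (2.43 to 12.2 FPKM) and COLEC12, a collectin gene, 4.22-fold (7.97 to 33.6 FPKM). SERF1A, HIST1H4J, GAGE2D, PVRIG2P, GAGE12I and GAGE5, the rest of the 12, are uncertain. SERF1A went from not listed to 20.2 FPKM while its near-identical copy SERF1B was at 57.9 and 48.8 FPKM.

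Stress and lipid lists did not share one direction with SR2211. The ATF4 and unfolded protein response list had a median of 0.25 (percentile 100), with 6 of 26 members at least 1.5-fold higher and none lower. DDIT4, an inhibitor of the mTOR kinase, was 2.36-fold higher (124 to 291 FPKM), ASNS, the asparagine synthetase gene, 1.93-fold (117 to 226 FPKM), SLC7A11, the cystine transporter gene, 1.93-fold (15.3 to 29.5 FPKM) and CHAC1, which encodes a glutathione-degrading enzyme, 1.86-fold (17.6 to 32.8 FPKM). The necroptosis, pyroptosis and ferroptosis list had a median of 0.51 (percentile 100), and its largest changes were those of SLC7A11 and CHAC1 and of CASP4, an inflammatory caspase gene (2.94 to 5.77 FPKM). Heat shock genes had a median of −0.13, with none of 11 past 1.5-fold. The NRF2 list had a median of 0.24, with 2 of 15 members at least 1.5-fold higher on the log2(FPKM + 1) scale and none lower. These were SLC7A11 and GCLC, the catalytic subunit gene of glutathione synthesis, which was 1.63-fold higher. Fatty acid synthesis genes had a median of 0.25 (percentile 99.97), with 4 of 13 at least 1.5-fold higher and 1 lower. Among them were SCD, a desaturase gene, 1.79-fold higher (263 to 470 FPKM), THRSP, 2.57-fold higher (2.47 to 6.36 FPKM), and ACSL3, an acyl-CoA ligase gene that androgen induces, 2.05-fold lower (96.7 to 47.2 FPKM). ABCG1, a cholesterol exporter gene, was 4.54-fold higher (2.43 to 11.0 FPKM, 3.73 to 5.58) in the LXR target list, whose median was 0.43 and whose other 6 members were within 1.5-fold. Cholesterol synthesis genes had a median of 0.08, with 21 of 24 within 1.5-fold and with TM7SF2 1.85-fold higher (109 to 202 FPKM). The hypoxia list had a median of −0.13, with 1 of 17 members at least 1.5-fold higher and 2 lower, and with NDRG1, which androgen also induces, 4.47-fold lower (76.0 to 17 FPKM).

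With SR2211 the mitosis list had a median of −0.23 and the S phase list −0.32, both at percentile 0, and no member of either was 1.5-fold lower on the log2(FPKM + 1) scale. MCM5, a replicative helicase gene, was 1.49-fold lower (65.4 to 43.9 FPKM) and KIF20A, a mitotic kinesin gene, 1.45-fold lower (26.6 to 18.3 FPKM). The DNA repair list was at −0.16, the MYC and E2F list at −0.25 and the replication-dependent histones at −0.36. The p53 targets had a median of 0.13, with GDF15, which encodes a stress cytokine, 2.09-fold higher (35.7 to 74.7 FPKM) and TP53INP1 1.99-fold higher (20.4 to 40.8 FPKM). For the clock and ROR list, which holds genes with ROR binding sites, the median was 0.02, with PER1 1.71-fold lower (6.44 to 3.76 FPKM) and NR1D1 1.55-fold higher (2.5 to 3.88 FPKM). No type 17 cytokine gene, the class RORγ controls in T cells, was expressed. In all, 137 expressed genes were at least 2-fold higher and 152 at least 2-fold lower, of which 67 and 81 were neither small RNAs nor genes with shared sequence. With a pseudocount of 0.1 FPKM in place of 1, 300 genes were higher and 214 lower.

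The combination was compared with vehicle to see what both drugs did together. Targets of p53, the transcription factor that DNA damage and other stresses activate, were the group furthest above vehicle. Of 26 expressed members 21 were at least 1.5-fold higher and 16 at least 2-fold higher, none was 1.5-fold lower, and the median log2 change was 1.24 (percentile 100). CDKN1A was 13.9-fold higher (47.7 to 664 FPKM, 13.2 to 14.6), GDF15 9.87-fold (35.7 to 353 FPKM, 9.19 to 10.6) and TP53I3, which encodes a p53-induced oxidoreductase, 12-fold (3 to 36.1 FPKM, 9.27 to 15.8). BTG2, an antiproliferative gene, was 5.03-fold higher (8.77 to 44.1 FPKM, 4.52 to 5.62).

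Mitosis genes were lower in the combination library than in the vehicle library. All 30 genes of the mitosis list were at least 1.5-fold lower and 27 at least 2-fold lower, with a median of −1.32 (percentile 0). CENPF, a kinetochore protein gene, was 3.92-fold lower (15.3 to 3.91 FPKM, 3.60 to 4.28), NUSAP1, a spindle protein gene, 3.71-fold (48.5 to 13.1 FPKM, 3.36 to 4.09) and MKI67, the proliferation marker Ki-67, 3.53-fold (20.4 to 5.76 FPKM, 3.31 to 3.78). In the S phase and DNA replication list 28 of 30 members were at least 1.5-fold lower, with a median of −1.10. RRM2, a subunit gene of ribonucleotide reductase, was 3.04-fold lower (60.6 to 19.9 FPKM, 2.84 to 3.26) and GINS1, a replication fork gene, 2.99-fold (24.6 to 8.23 FPKM, 2.68 to 3.34). DNA repair genes had a median of −0.75, with 10 of 20 at least 1.5-fold lower, among them BRCA2 (4.65 to 1.46 FPKM) and FANCI (21.5 to 7.49 FPKM). The MYC and E2F list was at −0.33, with the cell cycle regulator gene E2F1 2.30-fold lower (41.8 to 18.2 FPKM). In the list of senescence genes and cyclin-dependent kinase inhibitors, LMNB1, the lamin B1 gene, was 2.59-fold lower (63.3 to 24.5 FPKM), CDKN2C was 2.49-fold lower (19.1 to 7.65 FPKM) and IGFBP3 3.01-fold higher (3.12 to 9.40 FPKM), and the list median was −0.20.

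Tubulin genes, whose protein products docetaxel binds as microtubules, were higher in the combination. Of 10 expressed members 6 were at least 1.5-fold higher and none 1.5-fold lower, with a median of 0.77 (percentile 100). TUBB3, which encodes the class III β-tubulin, was 4.18-fold higher (9.48 to 39.7 FPKM, 3.67 to 4.78). TUBA4A was 2.52-fold higher (78.2 to 197 FPKM), TUBB2A 3.34-fold (5.90 to 19.7 FPKM) and TUBA1A 6.94-fold (0.62 to 4.30 FPKM), but these 3 share sequence with other tubulins and are uncertain. In the same library STMN1, which encodes the microtubule-destabilising stathmin, was 2.56-fold lower (74.1 to 29 FPKM, 2.35 to 2.79) and TPX2, a spindle assembly factor gene, 2.33-fold lower (46.7 to 20 FPKM), while MAPT, the tau gene, was 1.77-fold higher (4.65 to 8.22 FPKM). The median of that list of microtubule-associated genes was 0.14.

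Cell death lists differed from each other. Of 20 intrinsic pro-apoptotic genes 6 were at least 1.5-fold higher and none 1.5-fold lower, with a median of 0.19 (percentile 97.1). BBC3, which encodes the BH3-only protein PUMA, was 3.57-fold higher (2.63 to 9.38 FPKM, 2.77 to 4.63) and BID 2.07-fold (5.31 to 11.0 FPKM, 1.73 to 2.47), with PMAIP1, the NOXA gene, at 1.77-fold and BIK at 1.58-fold. In the death receptor list FAS was 3.25-fold higher (1.61 to 5.24 FPKM, 2.61 to 4.09) and the median was 0.36. The anti-apoptotic list had a median of 0.02, with BIRC5, the survivin gene, 2.62-fold lower (59.0 to 22.5 FPKM) and BIRC3 2.29-fold higher (0.93 to 2.13 FPKM). FTL, a ferritin gene, was 2.75-fold higher (138 to 381 FPKM) and CASP4 2.58-fold higher (2.94 to 7.58 FPKM) in the necroptosis, pyroptosis and ferroptosis list, whose median was 0.14. Several of these genes, BBC3 and FAS among them, are p53 targets as well.

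Androgen receptor targets were lower with the combination too. Of 27 members 19 were at least 1.5-fold lower and 15 at least 2-fold lower, with a median of −1.06. FKBP5, a co-chaperone gene induced by androgen, was 5.45-fold lower (121 to 22.1 FPKM, 5.15 to 5.78), C1orf116 5.41-fold (45.7 to 8.45 FPKM), SLC45A3 5.23-fold (26.6 to 5.09 FPKM), and KLK2 3.76-fold. Stress lists went in different directions. In the ATF4 list, whose median was −0.11 (−0.05 with GC bins removed), ATF3 was 2.60-fold higher (15 to 39.1 FPKM) and the chaperone genes HSP90B1 (755 to 377 FPKM) and PDIA4 (255 to 136 FPKM) were 2.00-fold and 1.87-fold lower. DDIT3, the CHOP gene, was 2.37-fold higher but shares sequence and is uncertain. HMOX1 was 4.48-fold higher (10.2 to 45.7 FPKM, 3.92 to 5.13) in the NRF2 list, which had a median of 0.22. In the autophagy and lysosome list (median 0.31, percentile 100) GABARAPL1 was 2.93-fold higher (9.24 to 27.1 FPKM) and MAP1LC3B 1.83-fold higher (21.2 to 38.7 FPKM). The immediate early list had a median of 0.53 (percentile 100), with JUN at 11.9 and 23.3 FPKM and JUNB at 40.3 and 80.2 FPKM, and the NF-κB list had a median of 0.43, with RELB at 0.99 and 2.29 FPKM.

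Among the 12 genes highest over vehicle, those with sequence of their own and not yet given were DIO3, a deiodinase gene, 29.9-fold higher (0.25 to 7.47 FPKM, 15.5 to 66.1), PLA2G2A, 19.9-fold (0.81 to 16.1 FPKM), GPNMB, a melanosome and lysosome glycoprotein gene, 13.1-fold (1.83 to 24.0 FPKM) and CA1, 10.0-fold (21.1 to 211 FPKM). SERF1A, HIST1H4J, GAGE12I and CEL (0.90 to 14.4 FPKM) are uncertain. MTPN, which went from not listed to 5.12 FPKM, is uncertain as well, because all of the sequence of LUZP6 (89.4 to 75.2 FPKM) is also found in other genes and LUZP6 lies within the MTPN transcript. Among the 12 lowest were PGC (9.72-fold), CHRNA2 (30.9-fold), ZNF385B (5.47-fold), ST6GALNAC1 (5.10-fold), ASRGL1 (4.67-fold), the neuropeptide gene NMU, 6.94-fold (13.4 to 1.93 FPKM), and GAGE6, which is uncertain. In all, 288 expressed genes were at least 2-fold higher and 332 at least 2-fold lower, of which 183 and 241 were neither small RNAs nor genes with shared sequence. The balance of the 2 directions depended on the treatment of low genes, and the share of higher genes, 46.5% here, went both ways. It was 34.6% with a mean of at least 5 FPKM (124 higher and 234 lower), 54.9% with a pseudocount of 0.1 FPKM (536 and 441) and 52% with no filter on the mean (420 and 387). The log2 change of the 6500 genes with a mean of at least 10 FPKM had a rank correlation of 0.23 with GC content here, 0.46 for the combination over docetaxel and 0.33 over SR2211.

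**Figure D2:**
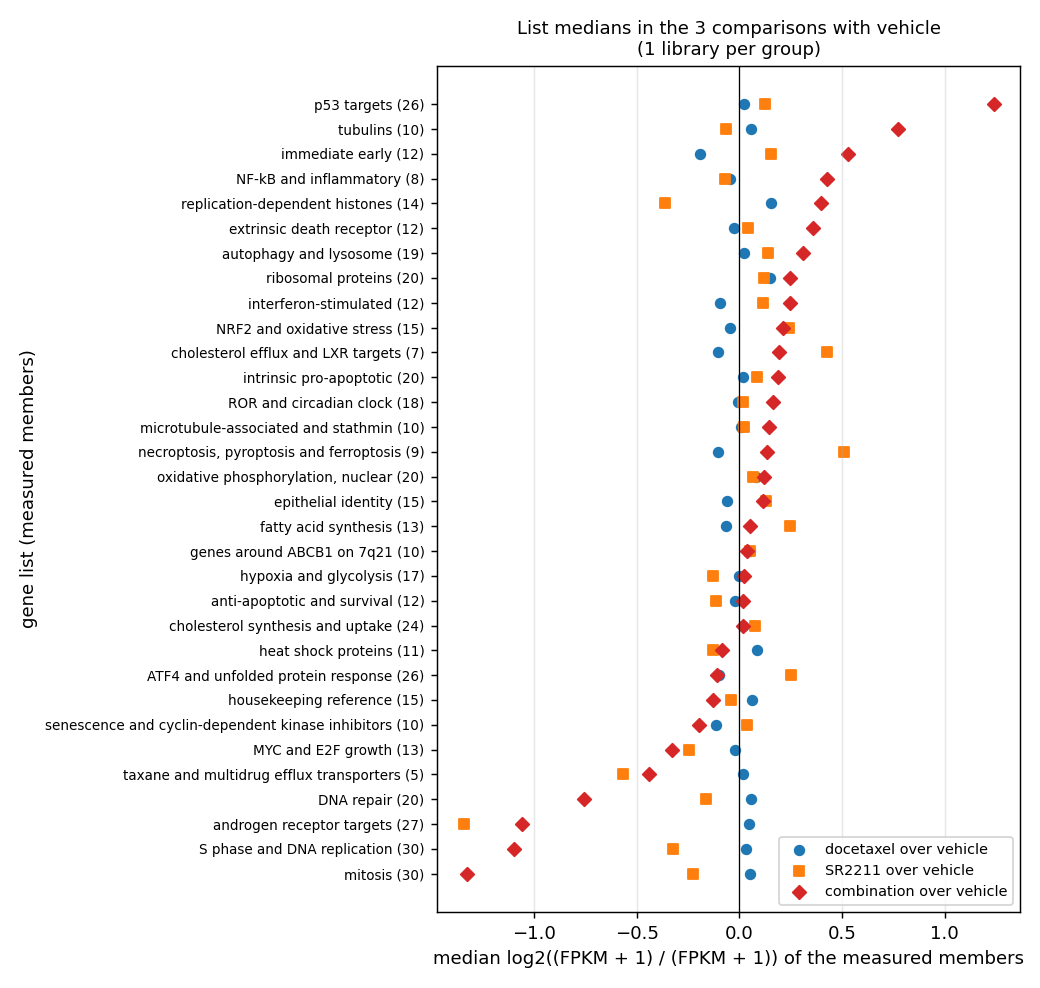
Median log2 change of the expressed members of each gene list with at least 5 such members, for docetaxel, SR2211 and the combination over vehicle, on the log2(FPKM + 1) scale with 1 point per list and comparison. The p53 targets (1.24), mitosis genes (−1.32) and S phase genes (−1.10) stood far from 0 in the combination, and the androgen receptor targets were at −1.34 with SR2211 and −1.06 with the combination.

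The combination was compared with docetaxel alone, which asks what the inhibitor changed in cells that also received the taxane. The groups that stood out over vehicle stood out over docetaxel as well, and both comparisons use the same combination library. The p53 targets had a median of 1.19, with 21 of 26 at least 1.5-fold higher, and the mitosis genes a median of −1.35, with all 30 at least 1.5-fold lower. CDKN1A was 11.0-fold higher (60.1 to 664 FPKM, 10.6 to 11.5), GDF15 12.3-fold (28.7 to 353 FPKM, 11.4 to 13.3) and GADD45A, a DNA damage response gene, 6.08-fold (4.74 to 28.8 FPKM, 4.94 to 7.54). HMMR, a mitotic spindle gene, was 3.57-fold lower (35.8 to 10.0 FPKM, 3.23 to 3.95). Androgen receptor targets had a median of −1.28, with FKBP5 5.79-fold lower (128 to 22.1 FPKM, 5.47 to 6.13). The S phase list was at −1.04, DNA repair at −0.76 and tubulins at 0.66. BBC3 was 4.62-fold higher (2.03 to 9.38 FPKM) and BAX, the pore-forming apoptosis gene, 1.76-fold (30.7 to 54.1 FPKM, 1.55 to 1.99). Heat shock genes had a median of −0.26, which was −0.12 with GC bins removed. Of 11 members 1 was at least 1.5-fold higher, HSPB1 (1110 to 1846 FPKM), and 1 lower, HSPE1. In all, 348 expressed genes were at least 2-fold higher and 329 at least 2-fold lower. With a pseudocount of 0.1 FPKM 658 genes were higher and 440 lower, and with a mean of at least 5 FPKM 157 and 233 were.

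The combination was compared with SR2211 alone, which asks what docetaxel changed in cells that also received the inhibitor. The p53 targets had a median of 1.07, with 22 of 26 members at least 1.5-fold higher, 14 of them at least 2-fold. CDKN1A was 12.5-fold higher (52.9 to 664 FPKM, 12 to 13.2), TP53I3 5.89-fold (6.12 to 36.1 FPKM, 4.87 to 7.19) and GDF15 4.72-fold (74.7 to 353 FPKM, 4.48 to 4.98). All 30 mitosis genes were at least 1.5-fold lower, with a median of −1.07, and TOP2A, the topoisomerase II gene, was 3.23-fold lower (24.0 to 7.44 FPKM, 2.96 to 3.52). S phase genes had a median of −0.75 and DNA repair genes −0.65. Tubulins had a median of 0.78, with TUBB3 4.10-fold higher (9.68 to 39.7 FPKM, 3.59 to 4.69). The replication-dependent histones had a median of 0.62, with HIST1H2BD 2.36-fold higher (31.7 to 74.7 FPKM). Androgen receptor targets had a median of 0.22 (percentile 99.99), with 4 of 27 at least 1.5-fold higher and 1 lower, among them PMEPA1 1.94-fold higher (5.16 to 9.99 FPKM) and MAF 4.45-fold higher (0.42 to 1.87 FPKM).

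Over SR2211 alone the ATF4 list had a median of −0.27 (percentile 0), with 7 of 26 members at least 1.5-fold lower and 2 higher. Among those lower were PSAT1, a serine synthesis gene, 1.91-fold lower (281 to 147 FPKM) and PHGDH, the first enzyme of that pathway, 1.76-fold lower (443 to 252 FPKM). The fatty acid synthesis list had a median of −0.28, with 2 of 13 members at least 1.5-fold lower and none higher, among them ELOVL6 2.17-fold lower (12.2 to 5.63 FPKM). SLC7A11 was 1.77-fold lower (29.5 to 16.7 FPKM). In all, 138 expressed genes were at least 2-fold higher and 177 at least 2-fold lower. Outside small RNAs and genes with shared sequence the counts were 57 and 91. With no filter on the mean they were 256 and 224, so the balance of higher and lower genes depended on the low genes.

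Each drug's change was then set against the same drug's change in the presence of the other, pairs of comparisons that share no library. For SR2211 the changes without and with docetaxel had Pearson's r = 0.51 and Spearman's rho = 0.56 across the 12780 expressed genes, which are not independent replicates. At least 2-fold, 59 genes were higher in both and 78 lower in both, where independent lists would share 3.73 and 3.91, and 25 went opposite ways. The largest shared increases outside shared sequence were those of CA1, 9.31-fold without and 9.56-fold with docetaxel, PLA2G2A, 12.1-fold and 26.4-fold, MATN2, 11.6-fold and 11.8-fold, and COLEC12, 4.22-fold and 4.2-fold. SERF1A and HIST1H4J also ranked among the highest 6 and are uncertain. The largest shared decreases included those of PGC, 18.3-fold and 11.0-fold lower, CHRNA2, 111-fold and 34.3-fold, ST6GALNAC1, 6.82-fold and 5.27-fold, C1orf116, 9.37-fold and 5.07-fold, and SLC45A3, 5.78-fold and 5.14-fold. Without small RNAs and genes with shared sequence r was 0.66, and 41 genes were higher in both, 58 lower in both and 0 opposite.

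For docetaxel the changes without and with SR2211 had r = −0.05 and rho = −0.07, and r = 0.02 and rho = 0.10 once the median change of each GC bin was removed. At least 2-fold, 9 genes were higher in both and 14 lower in both, where independent lists would share 0.59 and 0.94. Another 27 went opposite ways, for which no such number was computed. The genes with the largest shared increases were GAGE7, GAGE12I, CDC37L1-AS1, LOC101928402, NEDD8-MDP1 and DLG3-AS1, and those with the largest shared decreases were JMJD7-PLA2G4B, UQCRBP1, NSFP1, HIST1H2AJ, GSTT1-AS1 and UQCRHL. Of these 12, 9 are uncertain, and CDC37L1-AS1, LOC101928402 and DLG3-AS1 are non-coding. Without small RNAs and genes with shared sequence, 1 was higher in both, 0 were lower in both and 0 went opposite ways. The rest of the shared and opposite changes thus lay in small RNAs or uncertain genes.

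**Figure D3:**
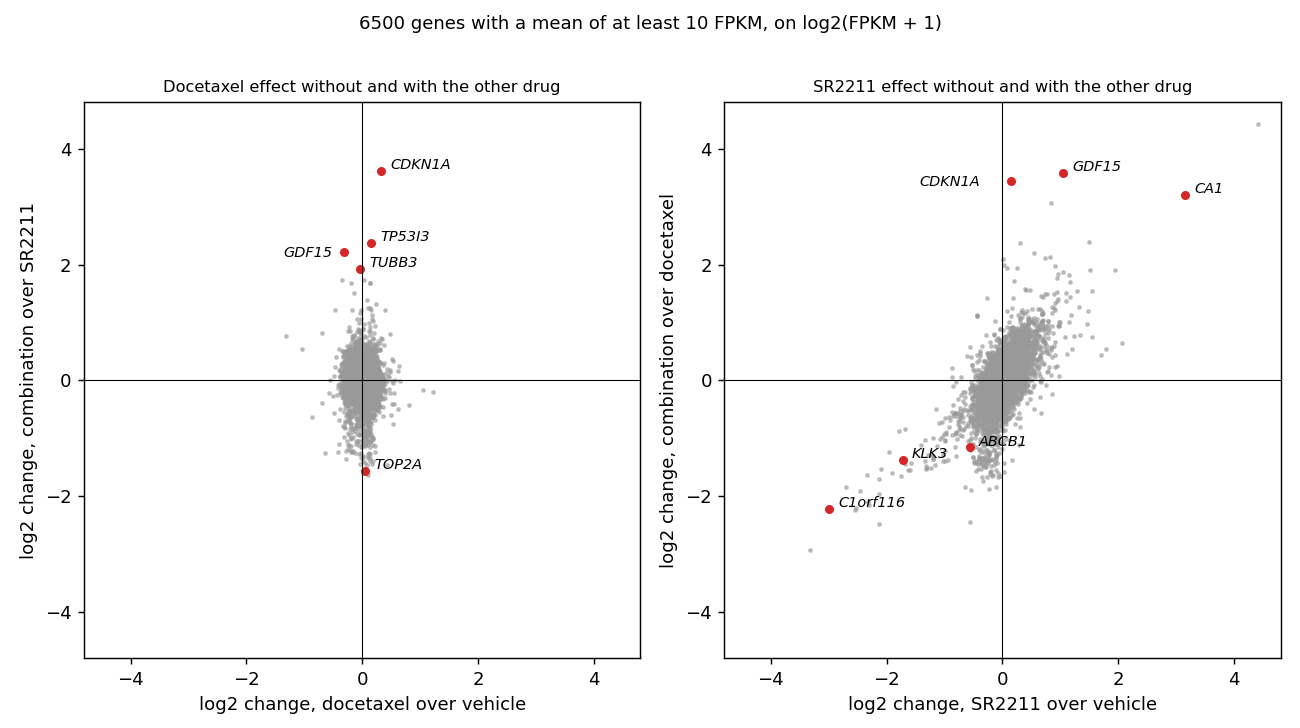
Log2 change on the log2(FPKM + 1) scale for each of the 6500 genes with a mean of at least 10 FPKM, with docetaxel (combination over SR2211 against docetaxel over vehicle) in one panel and SR2211 (combination over docetaxel against SR2211 over vehicle) in the other, 1 point per gene. Over all 12780 expressed genes r was −0.05 for docetaxel and 0.51 for SR2211.

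The 4 libraries form a 2 by 2 design, so the departure of the combination from the sum of the 2 single-drug log2 changes was computed for each gene, with no error estimate. It was at least 1 for 200 expressed genes and at most −1 for 209. CDKN1A stood highest with a departure of 3.30, and its levels were 47.7 FPKM with vehicle, 60.1 with docetaxel, 52.9 with SR2211 and 664 with the combination. DIO3 had a departure of 2.65, and the other four of the highest 6, CEL, SAPCD1, GTF2IP1 and HYPK, are uncertain. NMU had a departure of −1.97 and CENPF one of −1.73, and GAGE6, GAGE12I, MEF2B and PRH1, the other four of the lowest 6, are uncertain. By list, the median departure was 1.16 for p53 targets, with 14 of 26 members at least 1, and −1.13 for mitosis genes, with 20 of 30 at most −1. It was −0.70 for S phase genes, −0.62 for DNA repair genes, 0.72 for tubulins and 0.13 for androgen receptor targets. Outside small RNAs and genes with shared sequence the counts were 75 and 100.

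The remaining lists are given for the combination over vehicle. The epithelial list had a median of 0.12, with KRT19, a keratin gene, 2.20-fold lower (27.5 to 12.5 FPKM) and CLDN4, a tight junction gene, 1.47-fold higher (135 to 199 FPKM). The interferon list had a median of 0.25, with OAS3 2.37-fold lower (6.41 to 2.71 FPKM) and ISG15 1.45-fold higher (56.2 to 81.6 FPKM). Nuclear genes of oxidative phosphorylation were at 0.12, with NDUFB8 1.45-fold higher (81.3 to 118 FPKM), and the housekeeping reference genes at −0.13, with ACTB, the β-actin gene, 1.45-fold lower (2091 to 1439 FPKM). Neuroendocrine genes, which mark a lineage some treated prostate cancers adopt, had 3 expressed members. ENO2 was at 3.97 FPKM with vehicle and 7.34 FPKM with the combination, DLL3 at 7.53 and 7.31 FPKM and SYP at 1.34 and 1.61 FPKM. Among 4 expressed mesenchymal genes, FN1, the fibronectin gene, was 1.66-fold higher (16.8 to 28 FPKM), VIM, the vimentin gene, 1.82-fold higher (6.86 to 12.5 FPKM), SNAI1 was at 2.03 and 3.17 FPKM and ITGA5 at 3.63 and 4.87 FPKM. Mitochondrially encoded genes were not listed in any library. Of 37 markers of fibroblasts, endothelium, immune cells, basal prostate epithelium, red blood cells and androgen receptor-negative prostate cancer lines, 31 were listed and 6 had a mean of at least 1 FPKM, and the highest in the combination library was the lysosomal gene CD68 at 16.2 FPKM against 8.73 FPKM with vehicle.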

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

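Both tests in this part were chosen only after the result was seen. The combination library listed 1086 genes that no other library listed, against 244 listed only with vehicle, 254 only with docetaxel and 243 only with SR2211, so it stood out in genes that the comparisons leave aside. These 1086 genes had a median of 1 count and held 2544 reads together, 0.016% of the library. More reads are excluded as the reason, since the 15.95 M counts of the combination library were the fewest of the 4. Genomic DNA may have added reads, in which case olfactory receptor genes that are silent with vehicle would gain reads per kilobase to a similar extent as other silent genes. For the 44 olfactory receptor genes under 0.05 FPKM with vehicle, the gain over the single-drug libraries was 0.49 of that of 2453 other genes under that level (95% counting interval 0.19 to 0.82). The interval lies below an equal gain. It met neither the bound set for genomic DNA, which allowed a lesser gain, nor the bound set against it. These 44 held 35.9 reads with the combination, 17.04 with docetaxel and 14.5 with SR2211. Both sets hold only genes listed in some library, so silent genes with no reads anywhere are missing from the lengths. That raises both gains per kilobase by amounts not known here. With so few reads and this limit the ratio cannot decide, and genomic DNA stays open. No biological explanation was tested.

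Several genes went one way with a drug alone and the other way when the second drug was present, each by its log2 change in the presence of the second drug minus that without it. With 1 library per group none of these differences was tested. For SR2211 the difference was −2.86 for GAGE6, 1.65 for PLK2 (1.93 FPKM with vehicle, 1.62 with docetaxel, 0.84 with SR2211 and 4.17 with the combination), 2.63 for HYPK, 1.49 for FGF22 and 1.73 for URGCP-MRPS24. For docetaxel it was 1.67 for IFI27 (1.49, 0.52, 1.14 and 3.17 FPKM in the same order) and −1.85 for PRH1. This difference is the departure from additivity defined above, and in any gene it is the same number for both drugs. The drug named is the one for which the gene was flagged. SAPCD1, at 2.65, was flagged for both. GAGE6, HYPK, URGCP-MRPS24, PRH1 and SAPCD1 are among the genes called uncertain. IFI27 and FGF22 rested on few counts, 16 with vehicle and 5 with docetaxel for IFI27 and 25 and 7 for FGF22.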

How the results depend on the processing

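Requiring counting intervals to lie apart, removing GC bins and leaving out small RNAs and genes with shared sequence were chosen only after the result was seen. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Keeping the highest of repeated symbols was not run, since no symbol was repeated. No count of higher or lower genes can change direction. Of the list medians and named genes that were recomputed, none that stood at least 1.5-fold from no change did so. The correlation of the docetaxel changes without and with SR2211 lay between −0.06 and 0.02 as Pearson's r and between −0.10 and 0.10 as Spearman's rho. List medians were recomputed under 6 of the alternatives, not with counting intervals apart or with no filter, and 900 of 960 values moved by under 0.1 on the log2 scale. Without genes with shared sequence 3 tubulins were left, at a median of 0.57 in the combination over vehicle and 0.77 over SR2211, and 11 histones, at 0.54 and 0.93. Changes of some named genes were recomputed with the smaller pseudocount, on the TPM scale, with median-of-ratios factors and with GC bins removed. Of these, 305 of 516 values moved by under 0.1. They cover the genes tied to the treatment or the line and those named by rank in a comparison, a drug's 2 comparisons or additivity. Genes named only as list members, or after their values were seen, were not recomputed. On the TPM scale, with median-of-ratios factors and with GC bins removed, every count of genes in the 5 comparisons and past additivity stayed within 1.5 times its main value. The balance could still turn. The combination over docetaxel had 348 higher and 329 lower in the main setting and 420 and 413 on the TPM scale. It had 289 and 362 with median-of-ratios factors and 261 and 305 with GC bins removed. The 59 genes higher with SR2211 both without and with docetaxel numbered 92 on the TPM scale, 170 with a pseudocount of 0.1 FPKM and 34 with a mean of at least 5 FPKM.

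With a pseudocount of 0.1 FPKM the genes higher numbered 83 for docetaxel over vehicle, 300 for SR2211 over vehicle, 536 for the combination over vehicle, 658 over docetaxel and 238 over SR2211, and the departure from additivity had 353 genes above and 320 genes below, since a smaller pseudocount enlarges the changes of low genes. In that setting r of the SR2211 changes without and with docetaxel was 0.36. With no filter on the mean, which admits more genes, docetaxel over vehicle had 93 higher and 121 lower. The combination over SR2211 then had 256 higher and 224 lower, and 368 lay above additivity. With a mean of at least 5 FPKM, which admits fewer, docetaxel over vehicle had 9 higher and 10 lower, SR2211 over vehicle 55 and 68, and the combination over SR2211 44 and 99. In that setting the combination had 124 higher over vehicle and 157 over docetaxel, r was 0.63, and the departure from additivity had 57 genes above and 112 genes below.

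With counting intervals apart, docetaxel over vehicle had 9 higher and 12 lower, SR2211 over vehicle 81 and 95, and the combination over SR2211 84 and 107. Without small RNAs and genes with shared sequence the counts were 1 and 2 for docetaxel over vehicle, 67 and 81 for SR2211 over vehicle, 57 and 91 for the combination over SR2211 and 183 higher for the combination over vehicle, r was 0.66, and 75 lay above additivity and 100 below. The share of genes higher moved from 47.4% to 58.4% for SR2211 over vehicle and from 46.5% to 54.9% for the combination over vehicle with the smaller pseudocount. The causes of the shifts in r were not tested. Depth limits the low genes, since 1 FPKM rested on about 44.2 to 46.1 counts. In simulated counts for the combination over vehicle 76 unchanged genes among 12743 passed the 2-fold threshold by counting noise alone.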

Other observations

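The tests of the p53 and mitosis genes, and those of paralogs and GC content for tubulins, were chosen only after the result was seen, whereas the tests of tubulin autoregulation and of androgen-repressed genes were written before it was. The genes with sequence of their own that ranked next with SR2211 after those given above are named here after their values were seen. DHRS3, which encodes a retinaldehyde reductase, was 4.73-fold higher than with vehicle (2 to 9.46 FPKM, 3.51 to 6.48) and stood at 7.62 FPKM with the combination, and RBP5, a retinol-binding protein gene, was 4.47-fold higher (1.41 to 6.3 FPKM, 2.89 to 7.15). PDE2A, a cyclic nucleotide phosphodiesterase gene, was 7.3-fold higher (0.6 to 4.38 FPKM, 5.27 to 10.3), PRSS22, a serine protease gene, 5.22-fold (0.91 to 4.75 FPKM, 3.25 to 8.78) and FGF13, a fibroblast growth factor homologue gene, 3.89-fold (2.17 to 8.44 FPKM, 3.05 to 5). ATP1B1, a sodium pump subunit gene, was 2.99-fold higher (31.4 to 93.8 FPKM, 2.79 to 3.2), and CAMK2N1, which encodes an inhibitor of the kinase CaMKII, was 2.98-fold higher (42.2 to 126 FPKM, 2.82 to 3.15). Among 3 expressed metallothionein genes MT2A was at 132 FPKM with vehicle, 248 with SR2211 and 172 with the combination, MT1X at 57.1, 57.7 and 45.1 FPKM, and MT1F at 4.88, 6.88 and 6.41 FPKM.

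Further genes, also named after their values were seen, stood higher in the combination library than in the others. KRT75, a keratin gene, was not listed with vehicle or docetaxel and was at 0.03 FPKM with SR2211 and 4.03 FPKM with the combination. SERPINB5, the maspin gene, was at 0.09, 0.16, 0.21 and 3.67 FPKM with vehicle, docetaxel, SR2211 and the combination, NOS3, the endothelial nitric oxide synthase gene, at 2.24, 1.86, 3.15 and 11.8 FPKM, and FDXR, a mitochondrial reductase gene that p53 induces, at 16.6, 17, 19.9 and 68.1 FPKM. The ribosomal protein list had a median log2 change of 0.25 in the combination over vehicle (percentile 99.7), with RPLP1 1.37-fold higher (1687 to 2319 FPKM). Replication-dependent histones were at 0.40 over vehicle, opposite in sign to the mitosis and S phase lists, with HIST1H2BD 1.93-fold higher (38.8 to 74.7 FPKM).

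Docetaxel together with SR2211 may have raised p53 targets and lowered mitosis genes beyond what either drug did alone. Whether SR2211 acted through RORγ was not tested. GC content as the sole source is excluded, since the p53 median was 1.28 once the median of each GC bin was removed and the mitosis median −1.26. Library scaling is excluded as well, since the scaling factors of the combination and vehicle libraries differed by 0.0471 on the log2 scale and the lists moved in opposite directions. A difference between single cultures stays open, because each group had 1 library.

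Higher tubulin mRNA in the combination could follow from docetaxel acting on microtubules, since cells destroy α- and β-tubulin mRNA when free tubulin is plentiful and spare it when free tubulin is scarce. That predicts little change in γ-, δ- and ε-tubulin and γ-complex genes. The 8 such genes examined, which leave out the γ-tubulin gene TUBG1 of the tubulin list, had a median log2 change of −0.12 over SR2211. The median of 9 α- and β-tubulins was 0.78, but the 8 genes went both ways. TUBG2, a γ-tubulin gene that shares sequence, was at 0.53 over SR2211 and 0.96 over vehicle, and TUBE1, the ε-tubulin gene, was at −0.65 over SR2211. The median of the 8 genes met the prediction as written beforehand, which concerned the median alone. That each single gene should change little was a further condition, and TUBG2 and TUBE1 did not meet it. With 1 library per group this explanation stays open. Reads moving between paralogs are excluded as the whole source of the change over SR2211 and over vehicle. The summed α- and β-tubulin reads were at 5114 RPM with the combination, 3397 with SR2211, 3867 with vehicle and 4196 with docetaxel, log2 ratios of 0.59, 0.40 and 0.29. GC content is excluded as the sole source over SR2211 and over vehicle, since the tubulin median was 0.73 and 0.71 with GC bins removed. Over docetaxel it was 0.54, and there both explanations stay open, since the values lie between the bounds set for a cause and against it. With docetaxel alone the list was at 0.06.

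SR2211 may have lowered androgen receptor activity, in which case genes that androgen represses would be higher. The 5 such genes that were expressed had a median log2 change of 0.38 with SR2211, between the bound set for a cause and that set against it. DDC was at 6.47 FPKM with vehicle and 12.5 FPKM with SR2211, and SERPINI1 at 0.94 and 1.52 FPKM. UGT2B15, UGT2B11 and UGT2B28, which share sequence, went both ways. UGT2B15 was at 1.88 and 3.07 FPKM, but UGT2B11 fell from 2.31 to 0.64 FPKM and UGT2B28 from 1.82 to 0.56 FPKM. With the combination, where androgen receptor targets were lower too, all 5 stood above vehicle, by log2 changes of 0.33 (UGT2B28) to 1.59 (DDC). All 5 also stood above SR2211 alone, by 0.35 (UGT2B15) to 2.08 (UGT2B11), although the targets were not lower in that comparison. With so few genes, 3 of them uncertain, this stays open.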
